A study of Mus musculus with 2 samples.

How the data were processed

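The values used are counts of UMIs, as the authors deposited them and per the file headers. Per the labels' protocols, lungs of C57 mice with B16F10 metastases were digested with collagenase II and IV, red cells were lysed, and live CD45-positive, 7-AAD-negative cells were sorted. The protocols in the labels name both BD Rhapsody and 10x Chromium 3′ V3 chemistry, so the capture platform is uncertain. They give a target of 8000 cells and 20000 reads per cell and paired reads of 150 bp on an Illumina NovaSeq. Per the submitters' processing notes, reads were aligned to GRCm38 with Cell Ranger, and per the file headers its version was 7.2.0. The annotation release, the intron setting, the rule for calling cells and the number of animals per library are not given in the sources used here. The cell type label reads melanoma cell although the sort was for CD45. Other deposited text tables hold the same counts and were not used.

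The matrices held 55357.0 features and 10373 and 10156 barcodes, with a lowest depth of 500 and 503 UMIs, medians of 1485.0 and 1247.0 genes, and median mitochondrial shares of 1.38% and 1.65%. The first order is always the C435A tumour library, then the WT tumour library. Barcodes were kept with at least 200 genes, at least 500 UMIs and under 20% mitochondrial UMIs, which removed 102 and 157. Doublets were removed as the highest Scrublet scores at 0.8% per 1000 barcodes, 844 and 800 barcodes. The kept cells held 50269416 and 46523362 UMIs, with medians of 3200.0 and 2684.0 per cell.

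Counts were scaled to 10000 UMIs per cell and logged. The libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1 with seed 0. Immunoglobulin and T cell receptor segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of the variable genes. Clusters were named from 27 fixed marker sets, and the names carry the ending -like because no protein was measured. T cells were clustered again at resolution 1. The rule that named T subsets and the rule for clusters of low depth were set after the clusters were seen. Regulatory and gamma delta T clusters were named by their marker score, with a marker of their own among the leading genes. A cluster whose leading genes held more markers of another subset than of its own was left without a name. Of the rest, a cluster was CD8-like with UMIs of Cd8a or Cd8b1 in at least 50% of cells, or CD4-like with UMIs of Cd4 in at least 25% of cells, where that share was at least 4 times that of the other lineage.

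UMIs were summed over the cells of a class in each library and divided by the total of the class to give CPM. A class was compared with at least 200 cells in each library, which left 8 classes. Log2 ratios have exact conditional intervals for counting error, shares have exact Clopper-Pearson intervals, and list medians have intervals from 1000 Poisson draws. A count of 0 was set to a floor of 3 in a ratio. Of 24 fixed gene lists, members with at least 20 UMIs over both libraries were used, with at least 3 members per list. A list's percentile is its place among 10000 random lists matched on expression, which describes these libraries only. Members of a list are counted as higher or lower at 1.5-fold, and a single gene is called higher or lower where its interval excludes 0.

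Genes were named by a fixed rule in each class: at least 50 UMIs over both libraries and at least 50 CPM in one, then the 10 highest and the 10 lowest by the interval bound nearest 0, 160 entries in all, some of which are not reported here. The other genes in the text were picked from the fixed lists after values were seen. A gene is marked as possible free RNA where its level was at most 5% of that in the class with the highest level. This mark does not separate free RNA from whole cells of another class captured in the same droplet. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with shallower cells left out, beside the share in a class not thought to express the gene.

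The filters, clustering settings, marker sets, gene lists, naming rule and alternatives in the sensitivity part were chosen before the data were examined, apart from those described as added. Added after the data were seen were the T subset rule, the weighting of T clusters alike, the removal of cells with at least 2 UMIs of Cd3d, Cd3e, Cd3g and Trac, the further removal of monocyte-like cells with at least 2 UMIs of Ncr1, Klrb1c, Klre1, Klra4, Klra8, Eomes and Klri2, which are NK cell markers outside the cytotoxic effector list, the calling of CD8 and CD4 per cell, the choice of lists and genes to lead with, and every test of an explanation. A self-test drew Poisson counts from the summed UMIs of each class, with 200 genes changed by known amounts. The intervals held the true value for 94.0% to 97.5% of changed genes and 95.5% to 96.4% of the others. Of 200 unchanged lists, 7 to 12 fell outside the central 95% of random lists. The intervals assume the same Poisson counting, so this checks the calculation only. It does not cover genes whose UMIs come mostly from few cells.

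The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, statsmodels 0.14.6, matplotlib 3.10.9 and biopython 1.88, with R 4.3.3 and edgeR 4.0.16 for TMM factors alone. The place of Irf7 came from GENCODE M21 on GRCm38. Classes under the minimum size were left out of the main comparison and appear only among the further observations. Tumour cells outside the CD45 sort were not analysed here.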

Results

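Single-cell RNA sequencing was done on live CD45-positive immune cells sorted from lung tissue of C57 mice carrying metastases of B16F10, a mouse melanoma cell line. CD45 is a surface protein of nearly all white blood cells. The tumour cells carried either wild-type IRF7 or IRF7 with the change C435A, in which the cysteine named in the label is replaced by alanine. IRF7 is a transcription factor that drives production of type I interferons. The 2 libraries, 1 per group, are called the C435A tumour library and the WT tumour library below, after the genotype of the tumour cells and not of the immune cells. The C435A tumour library held 10373 barcodes and 59615672 UMIs (unique molecular identifiers, which mark single captured RNA molecules), with a median of 3401.0 UMIs per barcode. The WT tumour library held 10156 barcodes and 54934397 UMIs, with a median of 2785.0. After filtering, 9427 and 9199 cells were kept. With 1 library per group there is no replicate check on any difference reported here, and no test between the conditions was made. Every interval in brackets is a 95% interval that covers counting error only. Ratios are given as log2 of the C435A tumour library over the WT tumour library, so negative values are lower in the C435A tumour library.

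The title of the series places the question in tumour cells: whether nitrosylation of a cysteine of IRF7, in melanoma that expresses the nitric oxide synthase NOS1, affects immunity against the tumour. Irf7 (ENSMUSG00000025498) lies on the minus strand of chromosome 7 at 141262706 to 141266481 in GRCm38. In its transcript of 457 coding residues, the residue changed in C435A is a cysteine whose codon spans 141263294 to 141263296 in exon 10. The counts are of 3′ ends of RNA and do not read this codon, and the 50 and 83 melanoma-like cells held only 4 and 5 UMIs of Irf7, so the data do not check the genotype labels. Over all kept cells Irf7 had 1614 UMIs in the C435A tumour library and 1863 in the WT tumour library, a log2 ratio of -0.32 [-0.42, -0.22]. It was lower in CD8-like T cells (-0.69 [-0.92, -0.46]), B cell-like cells (-0.51 [-0.90, -0.12]) and alveolar macrophage-like cells (-0.70 [-1.06, -0.36]). In CD4-like T cells its ratio of -0.03 [-0.39, 0.33] and in monocyte-like cells that of -0.18 [-0.40, 0.03] had intervals that held 0. The share of cells with an Irf7 UMI, thinned to 1000 UMIs, gave less: 3.55% and 3.75% of CD8-like T cells (-0.204 points [-1.43, 0.971]), with intervals of the difference that held 0 in B cell-like and alveolar macrophage-like cells as well. This share was lower in neutrophil-like cells, 3.96% and 8.22% (-4.26 points [-7.96, -0.43]). In all T cells it was 3.70% and 4.76% (-1.05 points [-1.97, -0.14]), but 14.0% and 12.3% unthinned. Unthinned, it was 14.5% and 12.4% of CD8-like T cells, at median depths of 4621.5 and 3041.0 UMIs. With T clusters weighted alike, as described below, the CD8 ratio of Irf7 was -0.04. Nos1 had 4 and 12 UMIs over all kept cells, Nos2 had 4 and 1, and Ifnb1 had 1 and 1, so differences in these genes were not detectable at this depth. Ifng, which encodes interferon gamma, had 1930 and 585 UMIs, a log2 ratio of 1.61 [1.48, 1.75]. Of the chemokines that recruit T cells, Cxcl9 had 731 and 854 UMIs (-0.34 [-0.48, -0.19]) and Cxcl10 had 1512 and 1255 (0.16 [0.05, 0.27]).

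The first comparison asks how the makeup of the immune infiltrate differed between the tumours. NK cell-like cells made up 9.55% [8.96, 10.2] of kept cells in the C435A tumour library and 3.97% [3.58, 4.39] in the WT tumour library, a difference of 5.58 percentage points [4.87, 6.30]. Monocyte-like cells were also a larger share, 5.62% against 3.80% (1.82 points [1.21, 2.43]). B cell-like cells were a smaller share, 23.9% against 29.2% (-5.27 points [-6.53, -4.00]), as were macrophage-like cells outside the alveolar class, 1.42% against 2.89% (-1.47 points [-1.89, -1.06]). T cell-like cells had nearly the same share, 41.05% and 41.10%, with a difference of -0.05 points [-1.46, 1.36].

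Among the smaller classes, neutrophil-like cells were 3.04% and 4.10% (-1.05 points [-1.59, -0.52]), alveolar macrophage-like cells 7.85% and 6.90% (0.947 points [0.196, 1.70]) and plasma cell-like cells 2.91% and 2.03% (0.874 points [0.429, 1.32]). Conventional dendritic-like cells were 1.97% and 2.10%, and plasmacytoid dendritic-like cells 0.626% and 0.815%, with intervals of the difference that held 0. Melanoma-like cells passed the CD45 sort at 0.530% and 0.902%. Over all kept cells the 8 melanoma transcripts had a median log2 ratio of -1.35 [-1.45, -1.30], a value that includes the melanoma-like cells, which held 2103322 and 4596251 UMIs. In B cell-like cells that median was -1.49 [-1.81, -1.21] over 6 members. The 5 haemoglobin-related transcripts had a median of -2.05 [-2.17, -1.97] over all kept cells. Over the 4 of them that were measured it was 1.87 [1.502, 2.17] in CD8-like T cells and 0.45 in alveolar macrophage-like cells, and over all 5, with 1 at 0 UMIs in a library, -7.16 in CD4-like T cells. In CD8-like T cells of the C435A tumour library 1 cell gave 85.2% of the UMIs of Hbb-bs. With each library clustered on its own, the macrophage difference was -0.18 points, the T cell difference 2.40 points and the conventional dendritic difference -1.27 points. With no doublets removed, the alveolar macrophage difference was 1.88 points and the plasmacytoid dendritic difference -0.448 points. Shares are of sorted cells, so a difference in any class moves the shares of the others.

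**Figure D1:**
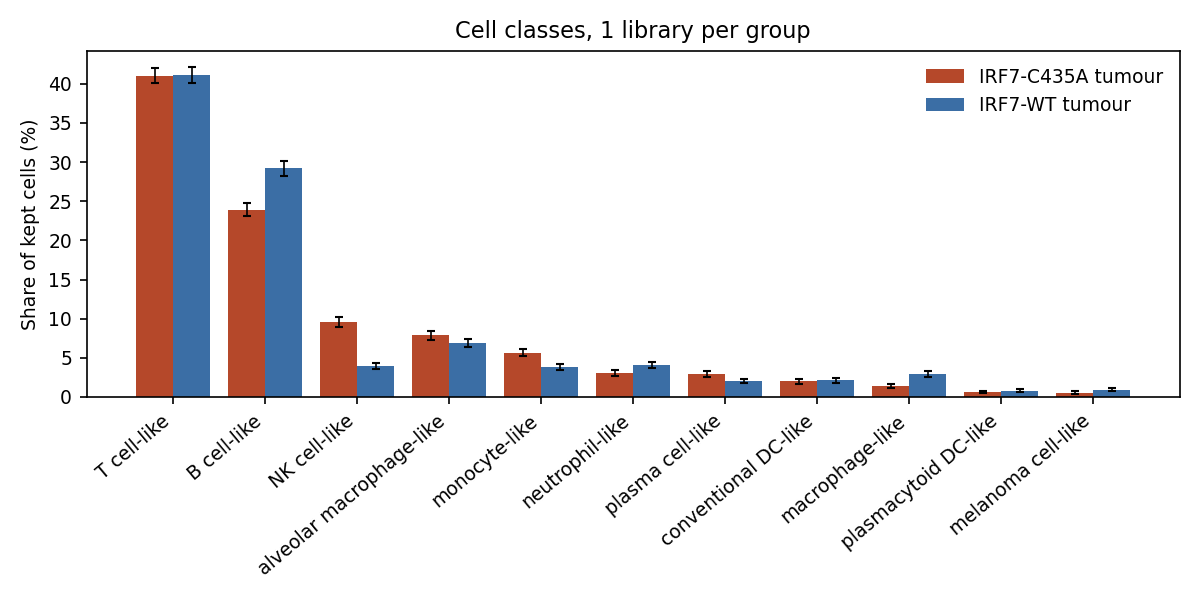
Share of kept cells (%, y axis) in each class of immune cells (x axis), for the C435A tumour library (9427 cells) and the WT tumour library (9199 cells). Bars start at 0 and give the share in 1 library each, with exact 95% binomial intervals for counting error only; NK cell-like cells stand at 9.55% against 3.97% and B cell-like cells at 23.9% against 29.2%.

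Within T cells, the subsets lay differently in the 2 tumours. CD8-like T cells, the cytotoxic lineage, were 57.4% [55.8, 58.9] of T cells in the C435A tumour library and 46.5% [44.9, 48.1] in the WT tumour library (10.9 points [8.66, 13.1]). CD4-like T cells, the helper lineage, were 23.6% [22.3, 24.99] and 33.2% [31.7, 34.7] (-9.57 points [-11.6, -7.56]). Regulatory T cell-like cells were 2.61% and 5.10% (-2.49 points [-3.37, -1.64]), and gamma delta T cell-like cells 1.47% and 0.820% (0.653 points [0.175, 1.15]). T clusters 6, 8, 10, 12 and 13, which the naming rule set after the clusters were seen left without a subset, held 14.9% and 14.4% of T cells. Of these, T cluster 12 was led by the interferon response genes Rsad2, Ifit3, Ifit1 and Isg15. It held 0.724% and 1.59% of T cells (-0.863 points [-1.37, -0.388]). Values of CD8-like and CD4-like T cells leave it out. T cluster 6 was left out because its leading genes held a marker of another subset, although 64.8% of its cells had UMIs of Cd8a or Cd8b1. T cluster 10, with Cenpf and Ube2c among its leading genes, had UMIs of Cd4 in 78.1% of cells. That share was under 4 times the 25.5% with UMIs of Cd8a or Cd8b1. T cluster 10 held 5.09% and 1.32% of T cells, so counting it as CD4-like would make the CD4 difference smaller. Cell cycle values of CD4-like T cells leave it out, while those of CD8-like T cells include T clusters 3 and 7, also led by genes of cell division.

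The subset shares depended on how T cells were assigned. With CD8 and CD4 lineages called per cell from UMIs of Cd8a, Cd8b1 and Cd4, CD8-like cells were 59.3% and 53.4%, while CD4-like cells were 21.3% and 19.4%, so the CD4 difference turned to 1.85 points. With T cells clustered at resolution 0.5, CD8-like cells were 39.3% and 52.1%, so the CD8 difference changed sign, and T cells left without a subset name were then 29.9% and 4.47%. At resolution 2 the CD4 difference was -5.33 points and the regulatory T cell difference -1.28 points, both nearer to 0 than above. Foxp3, the defining transcription factor of regulatory T cells, was seen in 0.582% and 1.10% of T cells thinned to 1000 UMIs, with 89 and 59 shallower cells left out, and in 1.52% and 2.75% unthinned. The share with a Foxp3 UMI in thinned B cell-like cells was 0% and 0.0377%, at median depths of 2112.0 and 1911.0 UMIs against 3696.0 and 2805.0 in T cells.

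CD8-like T cells of the C435A tumour library had more transcripts of cell division and of killing and fewer of the naive state. The proliferation genes Pclaf (10681 and 309 UMIs, 3.83 [3.66, 3.99]), Ube2c (3.78 [3.58, 3.99]), Ccnb2 (3.83 [3.54, 4.13]) and Birc5 (3.70 [3.50, 3.90]) led the genes that were higher. Gzmb, a granzyme that kills target cells, had 1067 CPM (counts of the gene scaled to the total of the class) against 127 (3.07 [2.96, 3.18]). The lymph node homing receptor Ccr7 (-2.33 [-2.46, -2.20]) was lower. The class was held by different T clusters in the 2 libraries: T cluster 0 held 24.3% of it in the C435A tumour library and 83.0% in the WT tumour library, T cluster 3 held 23.9% and 1.14%, T cluster 7 held 18.8% and 1.02%, T cluster 4 held 18.7% and 5.92%, and T cluster 5 held 14.2% and 8.94%.

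All 18 measured members of the cell cycle list were higher by at least 1.5-fold in CD8-like T cells of the C435A tumour library, with a median log2 ratio of 3.43 [3.30, 3.55] at percentile 100 of random lists. Besides the genes above, the rule for naming genes took Ccnb1 (3.95 [3.50, 4.43]), Ccna2 (3.67 [3.37, 3.99]), Cdk1 (3.57 [3.29, 3.87]), Cenpf (3.62 [3.29, 3.98]), Cdca8 (3.53 [3.25, 3.82]) and Tk1 (3.74 [3.25, 4.28]), all with roles in DNA synthesis or mitosis. Mki67 was seen in 16.2% [14.6, 17.8] and 1.21% [0.752, 1.85] of cells thinned to 1000 UMIs, with 49 and 24 cells left out, and in 40.8% and 3.30% unthinned. The share of thinned neutrophil-like cells with an Mki67 UMI, the reference, was 1.44% and 2.47%. That class includes a cluster led by Camp, Ngp and Ltf, with 48 and 103 cells. It was not shown to lack dividing cells, so its share is not a measure of background. In the WT tumour library T clusters 3 and 7, led by genes of cell division, held 1.14% and 1.02% of CD8-like T cells. Median depths were 4621.5 and 3041.0 UMIs in CD8-like T cells and 1663.0 and 1952.0 in neutrophil-like cells.

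Of 19 measured members of the cytotoxic effector list, 13 were higher by at least 1.5-fold and 1 lower, with a median of 0.96 [0.80, 1.03] at percentile 100. The granzymes Gzma (1.94 [1.90, 1.98]) and Gzmk (2.44 [2.29, 2.60]), the chemokine Ccl5 (1.17 [1.16, 1.19]) and Ifng (1.21 [0.98, 1.45]) were higher, Prf1 was at 0.48 [0.34, 0.63], and Tnf was the member lower by that size (-0.97 [-1.42, -0.52]). Gzmb was seen in 39.4% and 6.52% of thinned cells, in 59.5% and 9.50% unthinned, and in 1.30% and 0.264% of thinned B cell-like cells. Ifng was seen in 7.09% and 2.89% of thinned cells, in 24.3% and 5.18% unthinned, and in 0.135% and 0.113% of thinned B cell-like cells. These shares left out 49 and 24 cells, and B cell-like cells had median depths of 2112.0 and 1911.0 UMIs. Of the inhibitory receptors in the T cell exhaustion list, Lag3 (291 and 22 UMIs, 2.44 [1.81, 3.14]), Havcr2 (2.35 [1.69, 3.08]), Ctla4 (1.89 [1.52, 2.29]) and Pdcd1 (1.85 [1.27, 2.498]) were higher, while Tox, a transcription factor of exhausted T cells, was lower (-0.82 [-1.05, -0.58]). The list median was 1.78 [1.21, 1.92] over 10 members, with 8 higher and 2 lower by at least 1.5-fold. The T cell activation list had a median of 1.02 [0.62, 1.17], with the interleukin 2 receptor chain Il2ra (152 and 15 UMIs) higher.

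All 9 measured members of the naive and memory T cell list were lower by at least 1.5-fold, with a median of -1.73 [-1.84, -1.64] at percentile 0. Among them were Il7r, the receptor for the survival cytokine IL-7 (-2.01 [-2.10, -1.92]), Tcf7 (-1.70 [-1.79, -1.62]), Lef1 (-1.54 [-1.62, -1.47]) and Klf2 (-0.75 [-0.81, -0.69]). The naming rule also took Igfbp4 (-3.12 [-3.30, -2.94]), Treml2 (-2.87 [-3.18, -2.56]), Dapl1 (-2.64 [-2.74, -2.54]), Socs3 (-2.65 [-2.89, -2.40]), Ramp1 (-2.64 [-2.89, -2.40]), Itgae (-2.69 [-2.98, -2.40]) and Rflnb (-2.38 [-2.57, -2.19]). Spp1 (-3.35 [-3.66, -3.05]) was also taken, at 8.14 and 82.9 CPM against 5029 and 14807 CPM in macrophage-like cells, and is marked as possible free RNA.

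Interferon response genes were lower in CD8-like T cells, a class that leaves out T cluster 12, which was led by such genes. The type I interferon response list had a median of -0.69 [-0.83, -0.56] at percentile 0, with 2 of 43 members higher and 23 lower by at least 1.5-fold. Slfn5 (-2.36 [-2.74, -2.00]), Ifit1 (88 and 160 UMIs, -2.15 [-2.54, -1.76]) and Oas2 (-2.65 [-3.40, -1.95]) were lower, while Phf11b was higher (1.08 [0.89, 1.27]). The interferon gamma response list had a median of -1.10 [-1.22, -0.96], with 1 of 23 members higher and 15 lower, among them the GTPases Tgtp2 (-2.92 [-3.61, -2.28]) and Iigp1 (-2.17 [-2.59, -1.77]). Dissociation stress genes were lower too (median -0.62 [-0.74, -0.57]), led by the heat shock genes Hspa1b (-2.11 [-2.21, -2.01]) and Hspa1a (-2.01 [-2.10, -1.92]), whose sequences are close enough to share reads. Melanoma transcripts, which CD8 T cells do not make, had a median of -2.09 [-2.41, -1.78] over 6 members.

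These CD8 values move with the mix of T clusters. When the T clusters that had at least 50 cells in each library were given the same weight in both, an alternative chosen after the data were seen, the cytotoxic effector median was -0.03, the exhaustion median -0.10, the T cell activation median -0.19 and the naive and memory median 0.11, so these 4 changed sign, as did Il2ra (-0.35). The cell cycle median was then 0.80, the type I interferon median -0.22 and the interferon gamma response median -0.17, in the same directions as before but nearer to 0. With each library clustered on its own, the cell cycle median was 6.01, the cytotoxic effector median 2.185 and the exhaustion median 2.42. T clusters 3 and 7 had too few cells in the WT tumour library to enter this weighting. Their cells in the C435A tumour library had median depths of 8160.5 and 9920.0 UMIs, against 4621.5 in the whole class. They thus weigh more in the summed UMIs of the class than their shares of cells show. TMM scaling changed the log2 ratio of library sizes by -0.15 in CD8-like T cells, -0.14 in all T cells, 0.13 in alveolar macrophage-like cells and 0.30 in plasma cell-like cells, which moves every log2 ratio of the class as far the other way. Median ratio factors changed it by 0.12 in alveolar macrophage-like cells and 0.36 in plasma cell-like cells.

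**Figure D2:**
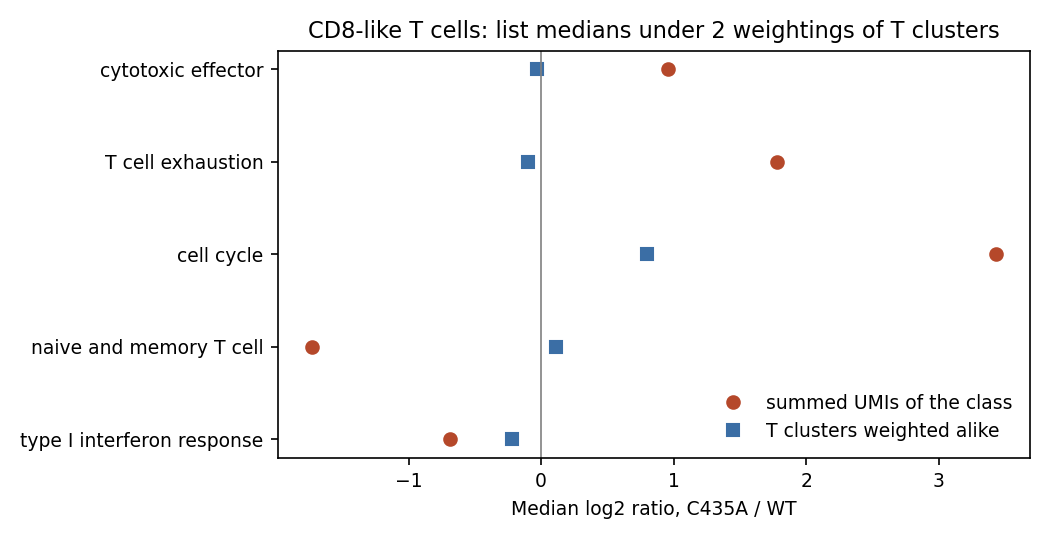
Median log2 ratio, C435A tumour library over WT tumour library (x axis), of 5 gene lists (y axis) in CD8-like T cells. Circles are from the summed UMIs of the class and squares from T clusters weighted alike; the cell cycle median goes from 3.43 to 0.80, and the cytotoxic effector median from 0.96 to -0.03.

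CD4-like T cells of the C435A tumour library had more effector transcripts. Gzmb had 355 and 19 UMIs (4.41 [3.74, 5.15]), Ccl5 was at 2.87 [2.79, 2.95], Nkg7, a cytotoxic granule protein, at 2.73 [2.57, 2.90] and Ifng at 2.22 [1.77, 2.69]. The calcium-binding genes S100a4 (3.36 [3.23, 3.49]) and S100a6 (3.28 [3.17, 3.38]), and the costimulatory receptor Icos (1.48 [1.26, 1.69]), one of the CD4 markers of the naming step, were also higher. Ccr7 (-0.99 [-1.16, -0.82]) was lower. T cluster 1 held 41.2% of the class in the C435A tumour library and 85.4% in the WT tumour library, and T cluster 2 held 58.8% and 14.6%.

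In CD4-like T cells 14 of 18 measured cytotoxic effector genes were higher by at least 1.5-fold and 0 lower, with a median of 1.33 [1.11, 1.82] at percentile 100. The naive and memory list had 5 of 9 members lower by that size and a median of -0.63 [-0.71, -0.49] at percentile 0. With each library clustered on its own these medians were 2.78 and -1.254, and in cells thinned to the same UMIs the naive and memory median was -0.33. The cell cycle list had a median of 1.18 [0.92, 1.52], with 15 of 17 members higher, and the T cell exhaustion list one of 1.54 [1.11, 2.10], with Lag3 (56 and 4 UMIs, 3.99 [2.55, 5.91]) and Ctla4 (2.34 [1.94, 2.75]) higher. Within T clusters 1 and 2 the exhaustion medians were 0.39 [-0.72, 0.71] over 3 members and 0.51 [-0.12, 0.98] over 7, with intervals that held 0. The cell cycle medians there were -0.07 [-0.37, 0.31] and 0.87 [0.67, 1.57]. The type I interferon list stood near 0 in this class, at -0.02 [-0.11, 0.12], with 8 of 42 members higher and 7 lower, and at -0.30 with each library clustered on its own. T cluster 12, led by interferon response genes, is not part of this class. The naming rule further took Plac8 (3.26 [3.06, 3.46]), Gzmk (2.72 [2.17, 3.31]), Gzma (2.91 [2.41, 3.45]) and Lgals1 (2.27 [2.16, 2.38]) among the higher genes, Gzma at 89.1 and 11.9 CPM against 16695 and 16756 in NK cell-like cells, and marked as possible free RNA. Among the lower genes were Igfbp4 (-1.52 [-1.67, -1.37]), Hspa1a (-1.59 [-1.71, -1.47]), Hspa1b (-1.35 [-1.49, -1.23]), Dapl1 (-1.38 [-1.56, -1.20]), Socs1, an inhibitor of cytokine signalling (-1.51 [-1.86, -1.16]), Treml2 (-1.45 [-1.88, -1.03]), Pdlim4 (-1.41 [-1.89, -0.96]), and Spp1 (-2.59 [-3.12, -2.09]) and Lyz2 (-1.66 [-1.81, -1.50]), both marked as possible free RNA.

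Gzmb was seen in 6.87% [5.29, 8.74] and 0.243% [0.0502, 0.709] of thinned CD4-like T cells, with 26 and 21 cells left out, and in 12.7% and 1.12% unthinned, with the B cell-like reference at 1.30% and 0.264% for the thinned cells. The WT tumour share thus lay at background. The median depths were 2678.0 and 2392.0 UMIs in CD4-like T cells and 2112.0 and 1911.0 in B cell-like cells. With the T clusters weighted alike the cytotoxic effector median was 0.32, and the naive and memory median was 0.01, a change of sign.

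NK cell-like cells differed in number but little in their killing genes. Gzma had a log2 ratio of -0.01 [-0.03, 0.02] with 16695 and 16756 CPM, Gzmb was at 0.10 [-0.0045, 0.21] and Prf1, the pore-forming perforin, at -0.12 [-0.21, -0.03]. Ifng stood at -0.26 [-0.52, 0.00], against 1.21 in CD8-like T cells, which turned to -0.74 with T clusters weighted alike, and 2.22 in CD4-like T cells. Ccl5 (33843 and 24604 CPM, 0.46 [0.44, 0.48]) and Klra8 (0.67 [0.53, 0.82]), an activating receptor of the Ly49 family whose close copies share reads, were higher, while the chemokines Xcl1 (-0.73 [-0.93, -0.53], with 40.6% of its UMIs in the WT tumour library from 1 cell) and Ccl3 (-0.57 [-0.73, -0.40]) were lower.

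In NK cell-like cells 1 of 17 cytotoxic effector genes was higher and 1 lower by at least 1.5-fold, with a median of -0.06 [-0.12, 0.01] at percentile 11.6. The type I interferon list had a median of -0.16 [-0.31, -0.0009] at percentile 4.22, with Isg15 at 47 and 38 UMIs (-0.97 [-1.62, -0.31]), and the cell cycle list one of 0.36 [0.08, 0.72], from low counts such as 65 and 10 UMIs of Ube2c (1.43 [0.46, 2.55]). The naming rule took Kdm6b (0.99 [0.52, 1.49]), Plac8 (0.97 [0.48, 1.49], marked as possible free RNA), the costimulatory receptor Tnfrsf9 (0.96 [0.45, 1.49]), Bscl2 (0.96 [0.43, 1.52]), Itgax (0.76 [0.43, 1.11]), Cbfa2t3 (1.00 [0.36, 1.70]), Mctp2 (0.95 [0.34, 1.61]) and the peptide transporter Tap1 (0.67 [0.31, 1.04]) as higher. As lower it took Kcnj8 (-1.44 [-1.94, -0.94]), Hspa1a (-1.03 [-1.27, -0.78]) and Hspa1b (-0.95 [-1.22, -0.69]), and the macrophage transcripts Apoe (-1.82 [-2.39, -1.254]), Fabp5 (-1.67 [-2.19, -1.15]), Lyz2 (-1.251 [-1.44, -1.06]), Spp1 (-1.35 [-1.76, -0.93]) and Ctsz (-1.249 [-1.80, -0.70]), all marked as possible free RNA. Cd3d, a T cell gene, was the last of these (-1.22 [-1.78, -0.66]), with 23.6% of its WT tumour UMIs in 1 cell. Without doublet removal the ratio of Apoe was 0.0083 and that of Cd3d 0.0026.

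B cell-like cells differed little. Among the genes taken by the naming rule, Plac8 (0.61 [0.56, 0.65]), Bcl2a1b, a survival gene of the BCL2 family with near-identical copies (0.87 [0.73, 1.02]), and the mitotic genes Birc5 (0.66 [0.53, 0.78]), Ccnb1 (0.76 [0.55, 0.97]) and Aurkb (0.72 [0.53, 0.91]) were higher. The stress gene Hspa1a (-0.78 [-0.87, -0.69]) was lower. The cell cycle list had a median of 0.48 [0.39, 0.52], with 4 of 18 members higher by at least 1.5-fold. For the type I interferon list the median was -0.11 [-0.18, -0.02], with 3 of 45 higher and 1 lower.

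The interferon-induced gene Ifi27l2a (-0.46 [-0.52, -0.40]) was lower in B cell-like cells, Isg15 was at -0.26 [-0.55, 0.04], and H2-K1, an MHC class I heavy chain, was higher (0.27 [0.24, 0.30]). The MHC class II list had a median of -0.11 [-0.16, -0.06]. The remaining named genes were Mtmr14 (0.72 [0.53, 0.91]) and S100a6 (-0.99 [-1.08, -0.90]), and transcripts marked as possible free RNA. Of those, Ccl5 (2.21 [2.02, 2.40]), Gzma (1.71 [1.42, 2.02]), Ly6c2 (1.15 [0.89, 1.41]) and Ighg3 (0.72 [0.55, 0.90]) were higher, and Spp1 (-2.87 [-3.20, -2.56]), Lyz2 (-1.56 [-1.65, -1.46]), S100a9 (-1.48 [-1.75, -1.22]), Igha (-1.17 [-1.30, -1.05]), Ctsd (-1.11 [-1.26, -0.96]), Lgals3 (-0.91 [-1.11, -0.72]) and Fabp5 (-0.86 [-1.06, -0.67]) were lower. With each library clustered on its own, the type I interferon median in B cell-like cells was 0.004.

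Alveolar macrophage-like cells of the C435A tumour library had fewer transcripts of alternative activation. Spp1, which encodes osteopontin, had 742 and 3082 CPM (-2.05 [-2.10, -2.01]), and Gpnmb (-1.03 [-1.11, -0.95]), Trem2 (-0.95 [-1.09, -0.82]), Igf1 (-1.77 [-1.98, -1.56]) and Msr1 (-1.42 [-1.63, -1.21]) were lower. The alveolar macrophage genes Ear1 (1.27 [1.19, 1.34]), Fabp1 (1.52 [1.41, 1.62]) and Cidec (1.23 [1.10, 1.36]) were higher, but they are among the markers that named this class. The inflammatory genes Cxcl2 (0.86 [0.74, 0.98]) and Nlrp3 (1.02 [0.80, 1.24]) and the checkpoint ligand Cd274 (0.69 [0.52, 0.86]) were higher. The mature neutrophil list, whose genes belong to another class, was higher too (0.60 [0.23, 0.78]), and at 0.0015 in cells thinned to the same UMIs.

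In alveolar macrophage-like cells the type I interferon list had a median of -0.29 [-0.42, -0.26] at percentile 0, with 2 of 46 members higher and 12 lower by at least 1.5-fold, including Oas3 (62 and 201 UMIs, -1.43 [-1.87, -1.02]) and Ifi27l2a (-1.19 [-1.28, -1.10]). The interferon gamma list had a median of 0.28 [0.11, 0.44] at percentile 96.5, with Gbp2 (0.86 [0.62, 1.10]) higher. Cxcl9 was at 0.85 [0.62, 1.09], with 33.1% of its 390 UMIs in the C435A tumour library from 1 cell. Its ratio changed sign to -0.22 in cells thinned to the same UMIs and to -0.023 averaged over cells. The alternative activation list had a median of -0.95 [-1.05, -0.82] over 7 members, of which 4 were lower by at least 1.5-fold and 0 higher. Dissociation stress genes were higher (0.57 [0.50, 0.62]), among them Egr1 (1.20 [0.97, 1.43]) and Fosb (1.10 [0.96, 1.248]). The type I interferon median was -0.64 in cells thinned to the same UMIs, -0.63 averaged over cells, -0.60 without cells with T cell UMIs and -0.47 with no doublets removed, so its size depends on these settings. Averaged over cells in place of summed, the interferon gamma median was -0.04, and with any gene of 1 UMI in each library admitted the alternative activation median was 0.05. The latter median was -0.53 in cells thinned to the same UMIs, -0.237 with no doublets removed and -1.08 with TMM factors.

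The naming rule also took Acaa1b (1.97 [1.74, 2.21]), Cpne5 (1.63 [1.43, 1.84]) and Epcam (1.55 [1.29, 1.82]) as higher in alveolar macrophage-like cells. It took Wfdc17 (-1.62 [-1.70, -1.54]), Mfge8 (-1.85 [-2.16, -1.54]), Crip1 (-1.24 [-1.30, -1.19]), Mmp14 (-1.41 [-1.66, -1.16]), Cxcl16 (-1.41 [-1.70, -1.13]) and the ferritin pseudogene Ftl1-ps1 (-1.41 [-1.59, -1.23]), which shares reads with its parent gene, as lower. Gzma (2.35 [2.14, 2.57]), Ccl5 (2.11 [2.00, 2.22]), Nkg7 (1.89 [1.63, 2.15]) and Ms4a4b (1.80 [1.58, 2.02]), transcripts of T and NK cells marked as possible free RNA, were higher, and 1 cell in each library gave 26.5% and 35.4% of the Gzma UMIs.

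Monocyte-like cells of the C435A tumour library had fewer transcripts of the type I interferon response. The class was a single cluster that scored highest for markers of nonclassical monocytes (2.87). F13a1, from the marker set of classical monocytes, was also among its leading genes. A different mix of the monocyte types in the libraries was not tested or corrected for. Usp18 (39 and 79 UMIs, -1.48 [-2.07, -0.91]), Slfn5 (-1.20 [-1.37, -1.03]), Isg15 (-0.79 [-1.05, -0.54]) and Ifi27l2a (-0.63 [-0.70, -0.56]) were lower. The MHC class I gene H2-K1 was higher (0.95 [0.89, 1.00]), as was Cd274 (158 and 42 UMIs, 1.45 [0.95, 1.98]), while H2-D1 (0.32 [0.27, 0.38]) and B2m (0.34 [0.30, 0.39]) stayed below 1.5-fold. H2-Q7 (2.02 [1.81, 2.22]) and H2-Q6 (2.34 [1.83, 2.89]) were higher too, but these paralogs share reads and their values are uncertain.

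In monocyte-like cells 2 of 46 type I interferon genes were higher and 22 lower by at least 1.5-fold, with a median of -0.55 [-0.64, -0.43] at percentile 0. The MHC class I list had a median of 0.30 [0.16, 0.36] at percentile 100, with 4 of 18 members higher by at least 1.5-fold and 0 lower, and the MHC class II list one of -0.48 [-0.58, -0.41], with Cd74 at -0.62 [-0.67, -0.58]. Cxcl10 was at 0.93 [0.50, 1.38] with 160 and 61 UMIs, and Cxcl9 at 0.66 [0.01, 1.33] with 65 and 30, of which 1 cell gave 96.7% in the WT tumour library. The cytotoxic effector list had a median of 2.96 [2.00, 3.08], led by Ccl5 (1622 and 115 CPM, 3.82 [3.62, 4.03]) and Gzmb (137 and 5 UMIs, 4.32 [3.06, 5.96]), genes of T and NK cells. Few cells carried it: 9.43% and 1.43% of the class held at least 10 UMIs of Ccl5 and gave 93.4% and 75.1% of them. Without cells that held at least 2 UMIs of Cd3d, Cd3e, Cd3g and Trac together, 16.4% and 8.57% of the class, this median was 0.94 and the type I interferon median stayed below 0. With cells holding at least 2 UMIs of 7 NK cell markers removed as well, the cytotoxic effector median was 0.30 and Ccl5 stood at 206 and 37.1 CPM, near its 173 and 37.4 CPM in B cell-like cells. The cell cycle list had a median of 1.23 [1.02, 1.87], with 13 of 14 members higher by at least 1.5-fold, and of 0.55 without the cells with T cell UMIs.

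Also higher among the named genes of monocyte-like cells were the lymphocyte genes Ctla2a (3.37 [2.66, 4.18]), Nkg7 (3.04 [2.60, 3.52]), Gzma (2.96 [2.58, 3.35], with 79.4% of its 63 UMIs in the WT tumour library from 1 cell), and Il2rb (3.18 [2.40, 4.09]), Cd28 (2.99 [2.20, 3.90]) and Ptprcap (2.26 [1.82, 2.73]). Nkg7 and Gzma, like Ccl5 and Gzmb, carry the mark of possible free RNA. Lower were Wfdc17 (-1.14 [-1.23, -1.04]), Ifi30 (-1.15 [-1.26, -1.04]), Cfp (-1.31 [-1.69, -0.94]), Vcan (-1.18 [-1.44, -0.93]), Tmem176b (-1.08 [-1.26, -0.91]), Mmp8 (-1.38 [-1.70, -1.07]), Mt1 (-1.43 [-1.83, -1.05]) and Spp1 (-2.13 [-2.75, -1.55]), the last 2 marked as possible free RNA. Ccl24 had 1 and 110 UMIs (-7.24 [-12.56, -4.73]), with 72.7% of the latter in 1 cell. Without doublet removal the ratio of Cxcl9 in this class was -1.249.

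In neutrophil-like cells of the C435A tumour library the type I interferon list lay lower. The class held 2 clusters in different shares: the deeper one, with the granule genes Camp, Ngp, Ltf and Mmp8, had 48 of 287 and 103 of 377 cells, and values of the class were not corrected for this. Rsad2, an antiviral enzyme, had 40 and 143 UMIs (-1.11 [-1.65, -0.60]) and Ifit1 had 16 and 55 (-1.05 [-1.96, -0.23]), whereas Isg15 was higher (0.63 [0.36, 0.90]) and Dhx58 had 15 and 16 UMIs (0.63 [-0.48, 1.75]). H2-K1 was higher (1.15 [1.03, 1.27]), and H2-Q6 (2.35 [1.67, 3.08]) and H2-Q7 (2.01 [1.66, 2.36]) were higher with the same uncertainty over shared reads. Of the cytokines, Il1b was at 0.46 [0.41, 0.51] and Cxcl2 at 0.29 [0.22, 0.35]. Cxcl3 had 0 and 51 UMIs; against the floor of 3 counts its log2 ratio was at least as low as -3.36.

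In neutrophil-like cells the type I interferon list had a median of -0.45 [-0.58, -0.21] at percentile 0, with 2 of 33 members higher and 13 lower by at least 1.5-fold, and -0.16 over members with at least 100 UMIs. The MHC class I list had a median of 0.21 [0.11, 0.54] at percentile 93.6, inside the central 95% of random lists, with 7 of 17 members higher by at least 1.5-fold. The myeloid inflammatory cytokine list had a median of 0.34 [0.25, 0.43] and the dissociation stress list one of 0.36 [0.30, 0.50], with Egr1 (0.98 [0.84, 1.12]) and Fosb (0.89 [0.70, 1.08]) higher. The naming rule took Olfm4 (1.51 [1.11, 1.91]), Stfa1, one of several near-identical stefin genes (1.46 [0.95, 1.98]), and Vnn3 (1.58 [0.78, 2.43]) as higher, besides Ccl5 (2.65 [2.18, 3.14]) and Gzma (3.11 [2.11, 4.25]), both marked as possible free RNA, of whose 182 and 52 UMIs in the C435A tumour library single cells gave 40.1% and 53.8%. It took Capg (-0.98 [-1.37, -0.61]), Ifitm6 (-0.69 [-0.83, -0.56]), Mmp8 (-0.62 [-0.75, -0.50]), Thbs1 (-0.86 [-1.22, -0.51]), H1f4 (-1.76 [-2.57, -1.03]), Klhdc4 (-1.45 [-2.45, -0.57]), Kmt5a (-1.02 [-1.59, -0.48]), and, marked as possible free RNA, Spp1 (-1.32 [-1.99, -0.71]) and H2-Ab1 (-0.99 [-1.45, -0.55]) as lower. Averaged over cells, the ratio of Cxcl2 was -0.02.

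**Figure D3:**
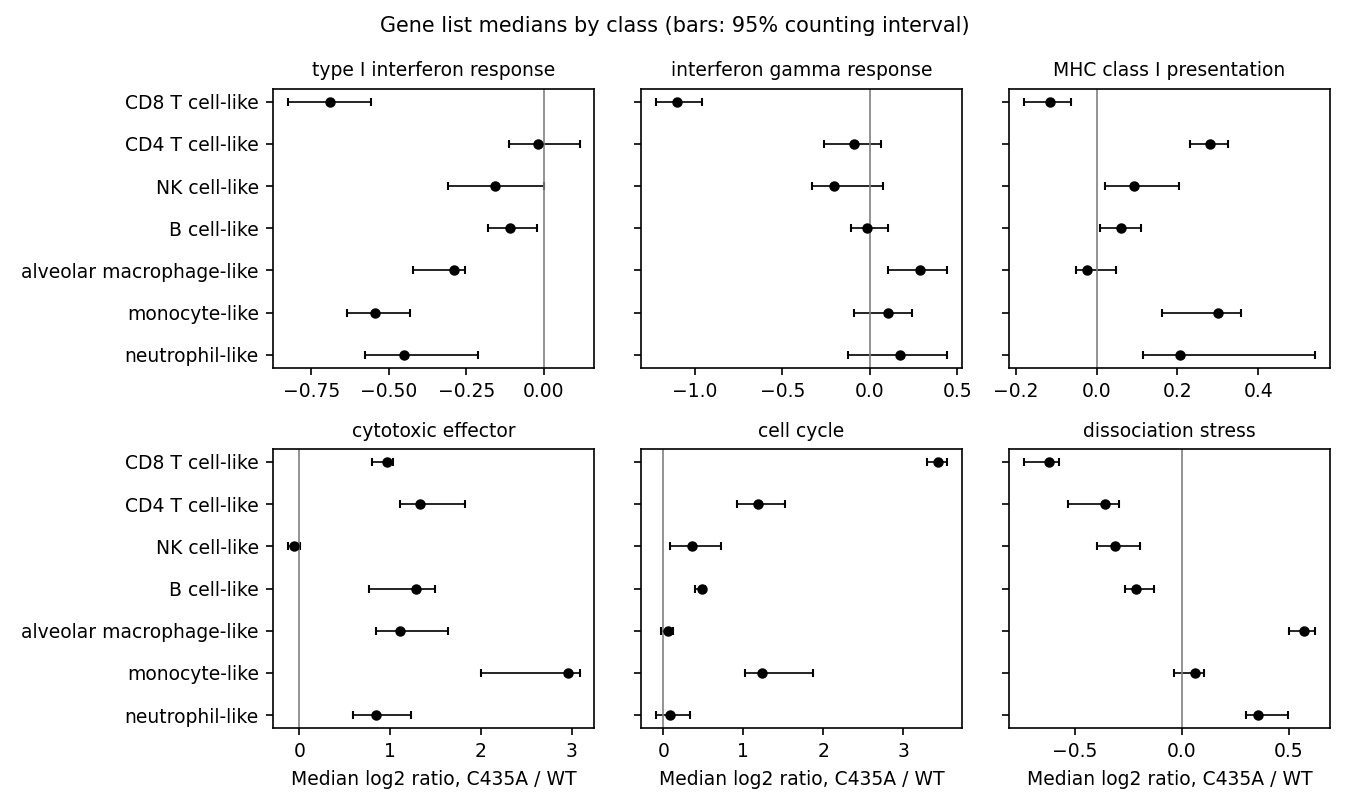
Median log2 ratio, C435A tumour library over WT tumour library (x axes), of 6 gene lists (panels) in 7 cell classes (y axis), with 95% counting intervals as bars. The type I interferon medians run from -0.69 in CD8-like T cells to -0.02 in CD4-like T cells, and the cell cycle medians from 3.43 in CD8-like T cells to 0.06 in alveolar macrophage-like cells.

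Set side by side, the type I interferon list median was below 0 with an interval that excluded 0 in CD8-like T cells, B cell-like cells, alveolar macrophage-like cells, monocyte-like cells and neutrophil-like cells. In NK cell-like cells the interval ended at -0.0009, and in CD4-like T cells it held 0, although with each library clustered on its own the CD4 median was -0.30 and the B cell median 0.004. Differences between classes were not tested. Over the T cells together, the naming rule took Gzmb (3.52 [3.42, 3.62]), S100a6 (2.86 [2.82, 2.90]), Ccnb2 (2.96 [2.80, 3.12]), Pclaf (2.82 [2.73, 2.91]), Gzmk (2.87 [2.73, 3.01]), Ccna2 (2.74 [2.58, 2.91]), S100a4 (2.61 [2.55, 2.67]), Birc5 (2.63 [2.53, 2.73]), Aurkb (2.72 [2.51, 2.93]) and Cdk1 (2.67 [2.51, 2.83]) as higher. As lower it took Igfbp4 (-2.34 [-2.45, -2.24]), Xcl1 (-2.25 [-2.45, -2.05]), Treml2 (-2.25 [-2.47, -2.03]), Dapl1 (-1.94 [-2.02, -1.87]), Hspa1a (-1.83 [-1.89, -1.76]), Hspa1b (-1.82 [-1.89, -1.75]), Socs3 (-1.87 [-2.02, -1.73]) and Ramp1 (-1.82 [-1.97, -1.67]), and Spp1 (-3.21 [-3.44, -2.98]), marked as possible free RNA.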

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

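No test of an explanation was made for these results. They stood out because a gene list was above 0 in a class and below 0 in another, in each case with an interval that excluded 0, and the difference between the classes was not tested. Dissociation stress genes had a median of 0.57 [0.50, 0.62] in alveolar macrophage-like cells, with Egr1 and Fosb higher, and of -0.62 [-0.74, -0.57] in CD8-like T cells, with Hspa1a and Hspa1b lower. Hypoxia and glycolysis genes had a median of 0.62 [0.55, 0.76] in CD8-like T cells, where Gapdh and Ldha were higher, and of -0.42 [-0.45, -0.35] in alveolar macrophage-like cells. With the T clusters weighted alike, the CD8-like median was -0.17, so the 2 classes then no longer went opposite ways. Myeloid inflammatory cytokines stood at 0.59 [0.28, 0.72] in alveolar macrophage-like cells with Cxcl2 higher, and at -0.97 [-1.33, -0.57] in CD8-like T cells. Mature neutrophil genes stood at 0.60 [0.23, 0.78] in alveolar macrophage-like cells and at -1.01 [-1.16, -0.14] in CD4-like T cells.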

How the results depend on the processing

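No paired analysis was possible because the groups share only replicate number 1, with 1 library each. A value was compared with its main value by its counting interval, and the cause was not tested. Values are percentage points for shares and log2 ratios or list medians otherwise. A change of sign was counted only where the main interval excluded 0, so the T cell share, at -0.05 points, is not in that count. Of 70 alternatives for 10 class shares 64 were the same, 6 moved and 0 changed sign. For 4 T subset shares 8 of 16 were the same, 4 moved and 4 changed sign. For 19 list medians described first 145 of 188 were the same, 36 moved and 7 changed sign, and for 23 others 161 of 227, 63 and 3. For 255 gene ratios 1715 of 2229 were the same, 489 moved and 25 changed sign, and for 55 shares with a UMI 17, 34 and 4.

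Settings added after the data were seen come first. With CD8 and CD4 called per cell, the CD8 T cell difference was 5.96 and the CD4 T cell difference 1.85, and after thinning 4.17 and 0.514. With T clusters weighted alike, CD8-like ratios were Cdk1 -0.098, Dapl1 0.082, Rflnb 0.099, Ifng -0.74, Prf1 -0.102, Nkg7 -0.0295, Pdcd1 -0.58, Ctla4 -0.083, Tox 0.252, Il7r 0.116, Tcf7 0.114, Lef1 0.259, Bach2 0.412, Isg15 0.0097 and Il2ra -0.35. The CD8-like medians were then type I interferon response -0.217, cytotoxic effector -0.0295, T cell exhaustion -0.103, naive and memory T cell 0.114, T cell activation -0.188, cell cycle 0.80 and hypoxia and glycolysis -0.167. In CD4-like T cells Lef1 was 0.269, cytotoxic effector 0.320, naive and memory T cell 0.0106 and T cell activation -0.059. Without cells with T cell UMIs, the alveolar macrophage type I interferon response was -0.60.

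With Leiden resolution 0.5 the macrophage difference was -1.98. With T cells at resolution 0.5 the CD8 T cell difference was -12.9 and the gamma delta T cell difference -0.233, and at resolution 2 the CD4 T cell difference was -5.33 and the regulatory T cell difference -1.28. With each library clustered on its own, T cells differed by 2.40, macrophages by -0.179 and conventional DC by -1.27, CD8-like cytotoxic effector was 2.185, exhaustion 2.42 and cell cycle 6.01, CD4-like type I interferon response -0.304, cytotoxic effector 2.78 and naive and memory T cell -1.254, and B cell type I interferon response 0.0036. With no doublets removed, alveolar macrophages differed by 1.88 and plasmacytoid DC by -0.448, NK cell Apoe was 0.0083 and Cd3d 0.0026, monocyte Cxcl9 -1.249 and neutrophil Cxcl10 -0.60, and the type I interferon response was -0.1895 in B cells and -0.47 in alveolar macrophages, where interferon gamma response was 0.456 and alternative activation -0.237. Under 10% mitochondrial UMIs, CD4-like naive and memory T cell was -1.01.

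With TMM factors, CD8-like type I interferon response was -0.54, cytotoxic effector 1.11, exhaustion 1.93, naive and memory T cell -1.58 and cell cycle 3.58, and alveolar macrophage alternative activation -1.08, also -1.08 with median ratio size factors. With at least 1 UMI in each library that median was 0.045, and with at least 100 UMIs the neutrophil type I interferon response was -0.156. With cells thinned to the same UMIs, Cxcl10 was 0.182 in T cells and -0.23 in B cells, Cxcl9 in alveolar macrophages -0.22, CD8-like type I interferon response -0.54, naive and memory T cell -1.11 and cell cycle 3.71, CD4-like naive and memory T cell -0.334, alveolar macrophage type I interferon response -0.64 and alternative activation -0.53, and monocyte type I interferon response -0.66. With the mean over cells, CD8-like type I interferon response was -0.465, cytotoxic effector 1.03, naive and memory T cell -1.09 and cell cycle 3.61, CD4-like naive and memory T cell -0.362, Cxcl9 in alveolar macrophages -0.023, type I interferon response -0.63 and interferon gamma response -0.040 there, and Cxcl2 in neutrophils -0.022. With no thinning, the differences in the share with a UMI were 0.0958 for Tox and 0.361 for Isg15 in CD8-like T cells, and 0.447 for Isg15 and 1.71 for Irf7 in T cells.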

Other observations

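The classes in this paragraph lay below the minimum size set for the main comparison, and no test of an explanation was made for them. Macrophage-like cells outside the alveolar class (134 and 266 cells) had more MHC class II transcripts, which present antigen to CD4 T cells: H2-Eb1 was at 1.00 [0.95, 1.05], H2-Aa at 0.90 [0.85, 0.94] and Cd74 at 0.63 [0.59, 0.66], with a list median of 0.63 [0.59, 0.72]. Their interferon gamma list stood at 0.35 [0.19, 0.48] and their type I interferon list at -0.37 [-0.54, -0.24], with 17 of 45 members lower by at least 1.5-fold and 0 higher. In regulatory T cell-like cells (101 and 193 cells) the type I interferon list went the other way, at 0.39 [0.24, 0.61], with Isg20 (31 and 32 UMIs, 1.14 [0.38, 1.90]) and Usp18 (19 and 10 UMIs, 2.11 [0.93, 3.38]) higher. Plasma cell-like cells (274 and 187 cells) held 2 clusters in different shares, 1 of them with 121 and 51 cells, and had less of the antibody genes Ighg1 (-1.46 [-1.49, -1.43]), with 17.2% and 15.3% of its UMIs in 1 cell, and Igha (-0.87 [-0.88, -0.86]), and more cell cycle transcripts (0.96 [0.89, 1.05], where matched random lists had a median of 0.44). Conventional dendritic-like cells (186 and 193 cells) had more cell cycle transcripts as well (1.74 [1.55, 1.89]). They held a cluster of 117 and 103 cells and a mature dendritic-like cluster of 69 and 90 cells, and this mix was not corrected for.

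Melanoma-like cells that passed the sort (50 and 83 cells) had more Cxcl10, at 351 and 157 UMIs (2.29 [2.01, 2.57]), and an MHC class I median of 0.56 [0.45, 0.73], with 7 of 16 members higher by at least 1.5-fold. Their cytotoxic effector median of 2.35 [1.80, 2.88] and immunoglobulin median of 1.13 [0.68, 1.65] were also higher, and these are transcripts of lymphocytes. Spp1 over all kept cells had 13796 and 87064 UMIs (-2.77 [-2.80, -2.74]), and it was lower in every class compared. In all of these but alveolar macrophage-like cells it is marked as possible free RNA. Its level was highest in macrophage-like cells outside the alveolar class (5029 and 14807 CPM), which were also a smaller share (1.42% against 2.89%). The lower values in the marked classes may thus not be separate observations. The club cell gene Scgb1a1 had 196 and 6952 UMIs over all kept cells, with 95.6% of the latter in 1 cell.

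All tests of explanations in the next 3 paragraphs were chosen only after the result was seen. Cell cycle transcripts such as Pclaf and Mki67 were higher in CD8-like T cells of the C435A tumour library. Free RNA of cycling cells alone is argued against, since the difference in list CPM was 7.61 times that in B cell-like cells (6192 and 791 CPM against 2969.6 and 2260 CPM). A shift of the whole library by the same amount in every class is argued against by the cell cycle median of 0.057 [-0.024, 0.116] in alveolar macrophage-like cells, although the list was also higher in other classes, among them monocyte-like cells (1.23 [1.02, 1.87], and 0.55 without cells with T cell UMIs), CD4-like T cells (1.18 [0.92, 1.52]) and B cell-like cells (0.48 [0.39, 0.52]). The IRF7 genotype of the tumour and the animal or preparation of the library cannot be told apart with 1 library per group, and the genotype stays open as an untested hypothesis.

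The type I interferon list, with Ifit1 and Slfn5, was lower in CD8-like T cells of the C435A tumour library. Among T clusters 0, 4 and 5, their mix as the whole cause is argued against: weighted alike, the median over 43 members was -0.22 [-0.28, -0.09]. This was less far from 0 than the -0.69 of the summed class. For that class the mix stays open, since T clusters 3 and 7, 23.9% and 18.8% of its cells in the C435A tumour library, did not enter. Their cells were deeper than those of the whole class, so they weigh more than this in its summed UMIs. The weighting cannot see a mix of states inside a cluster either. Within T cluster 0 the median was -0.16 [-0.27, -0.05], and within T clusters 4 and 5 the intervals held 0. Less free RNA of interferon genes cannot be told apart from a lower response in the cells: the difference in list CPM in T cluster 1 was 0.44 of that in CD8-like T cells (2875 and 3217 CPM against 2211 and 2986 CPM), and the counting error of this ratio keeps it open. The IRF7 genotype of the tumour and the animal stay open as well, untested.

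Cytotoxic transcripts, led by Ccl5, were higher in monocyte-like cells of the C435A tumour library. Whether T cells captured with monocytes, or T and NK cells, were the whole cause could not be decided. Without cells with at least 2 UMIs of Cd3d, Cd3e, Cd3g and Trac, the median over 12 members was 0.94 [0.48, 1.39]. Without cells with at least 2 NK marker UMIs as well, it was 0.30 [0.09, 0.82] over 10 members. Both intervals lay above 0, but captured cells with fewer such UMIs were not removed. The list median was also above 0 in B cell-like cells, at 1.28 [0.77, 1.49]. Free RNA alone is argued against by a difference in Ccl5 that was 11.1 times that in B cell-like cells (1622 and 115 CPM against 173 and 37.4 CPM). Captured T and NK cells together with free RNA stay open as a candidate explanation, since without those cells, 17.7% and 9.14% of the class, the difference in Ccl5 was 1.252 times that in B cell-like cells, with Ccl5 at 206 and 37.1 CPM, Gzma at 35.5 and 6.92 against 52.8 and 16.1, and Nkg7 at 17.5 and 4.40 against 30.1 and 10.04. The genotype of the tumour was not tested.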
